A study of Mus musculus with 14 samples.

How the data were processed

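Gene expression was measured on Affymetrix mouse oligonucleotide arrays, 1 biotin-labelled sample per array, in bone marrow cells (BMCs) sorted as positive for the surface antigen Sca1 and negative for the receptor cKit. The mice bore a Matrigel implant without tumour cells, an instigating tumour or a non-instigating tumour of matched size. Per the labels, total RNA was extracted with Qiagen kits and labelled with the NuGen Ovation biotin system. Sample titles gave the groups, with 4 Matrigel, 5 Instigator and 5 Non-instigator arrays. Nothing in the labels says that the arrays come from separate animals, so p-values measure the spread between these samples, which may be technical. The labels give no batch, date or animal. The description of the array titled Instigator 5 names the other tumour type. It was kept in the Instigator group by its title and source characteristic, and fits without it or with it moved were run as alternatives.

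The deposited table holds linear intensity values of 22690 probe sets on 14 arrays. Per the submitters' processing notes, the authors used RMA in the affy package under R 2.11.0. RMA as a method corrects the background, normalizes between arrays and summarises the probes of a set, and the options used are not given in the sources used here. The deposited intensity values were not normalized again. Median intensity per array ran from 119 to 145. The number of arrays limits the precision, and the scanner images and probe-level values were not used here. Log2 was taken of the deposited intensity values, and all tests were run on that scale.

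The 64 array control probe sets were left out of the tests, which leaves 22626. Gene names came from the platform annotation. 20380 probe sets carry 1 gene symbol, 691 carry several and 1555 are unnamed here, and a probe set with several symbols was never named. Of the probe sets with 1 symbol, 20351 were found in the mouse reference table of assembly GRCm38.p6, and 0 symbols needed an update. That table was used for names alone, since the array table names no genome build. A gene stands for its probe set with the highest mean over the 14 arrays, which gives 12393 genes. Ly6a, which encodes Sca1, has no probe set named for it alone in the annotation and is not analysed here.

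Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, with no trend and no robust estimation). All 14 arrays entered 1 fit with group as the factor. The 3 comparisons were Instigator against Matrigel, Non-instigator against Matrigel, and Instigator against Non-instigator. P-values were adjusted by Benjamini-Hochberg over the 22626 probe sets, and a probe set was called at an adjusted p under 0.05. Counts at an unadjusted p under 0.05 are descriptive. The text names Grn and Kit always, and for each comparison the 10 genes per direction with the smallest p, as fixed for the case of fewer than 5 called genes. It also names up to 4 members of a gene list by size of difference. Values for Grn and Kit also carry two-sided exact permutation tests.

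Of the 25 gene lists tested, 13 hold cell type markers, 11 hold genes of a process and 1 holds sex-linked genes. They were fixed before the data were examined, as were the groups, the tests and most alternatives. Of 476 listed genes, 414 are measured. Each list was tested against the other genes with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 25 lists. The test was repeated with a correlation estimated for each list. An exact permutation test of the mean of each list per array was added after the data were seen.

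The gene test was tested on simulated data with the real means and spreads, 22626 probe sets and 200 changed ones. For Instigator against Matrigel it called 44% of the probe sets changed by 0.5 on the log2 scale, 94% of those changed by 1, 98% at 1.5 and 100% at 2. For Non-instigator against Matrigel the shares were 56%, 94%, 100% and 98%. For Instigator against Non-instigator they were 44%, 90%, 98% and 100%. In a simulation over 12393 genes, the list test called a T cell list shifted by 0.5 in the Instigator arrays in both comparisons with those arrays, and called 0 of the other lists. The simulated noise was independent between genes. In the data the correlation estimated within a list ran from 0.0116 to 0.603, so the 0 false calls do not describe the list test here.

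The alternatives were the groups compared alone, the brighter set of probe sets, quantile normalization, centring on the median, an intensity trend with robust estimation, array weights, the replicate number as a block, leaving out each array, Instigator 5 moved to the other group, and the mean of a gene's probe sets. Leaving out Instigator 4 and Matrigel 3 together, and scaling before the list test, were added after the data were seen. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.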

Results

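Expression was profiled in Sca1-positive, cKit-negative bone marrow cells from mice carrying Matrigel (n = 4), an instigating tumour (Instigator, n = 5) or a size-matched non-instigating tumour (Non-instigator, n = 5). Matrigel is a basement membrane extract that here served as the tumour-free implant. An instigating tumour is one that promotes the growth of other, otherwise indolent tumour cells at a distance in the same host. Differences are on the log2 scale of RMA intensity, where a difference of 1 is a doubling. A preset correlation between genes was assumed in the list tests named below unless an estimated correlation is stated.

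Across the 14 arrays, Instigator 4 and Matrigel 3 stood apart. On Instigator 4 the beta-actin control probe sets gave a 5' minus 3' difference of -3.41, against -0.81 to -0.51 on the other 13 arrays, and the Gapdh control gave -4.03 against -1.16 to -0.73. The transferrin receptor control gave -2.58 on Instigator 4, inside the range of -2.71 to -1.98 on the others. Instigator 4 lay at 73.8 on the first principal component, which held 35.4% of the variance, while the others lay between -19.6 and 7.98. Matrigel 3 had a median log2 intensity of 7.18, against 6.90 to 7.01 elsewhere, and lay at -55.7 on the second component (19.3% of the variance). Median intensity per array ran from 119 on Instigator 4 to 145 on Matrigel 3. No 2 arrays were identical, and the closest of the 91 pairs, Matrigel 2 and Non-instigator 3, had a median absolute difference of 0.0954.

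**Figure D1:**
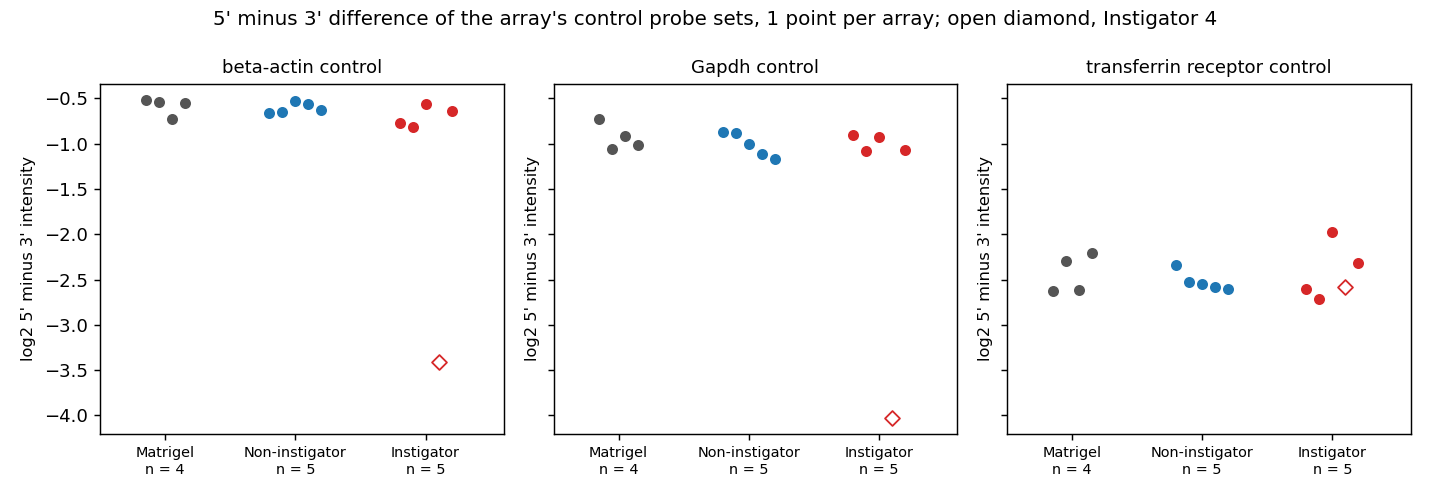
Difference between 5' and 3' control probe sets (log2 intensity, y axis) for beta-actin, Gapdh and the transferrin receptor, 1 point per array by group (x axis), with Instigator 4 as the open diamond. Instigator 4 lies at -3.41 for beta-actin and -4.03 for Gapdh, below every other array, and at -2.58 for the transferrin receptor, among the others.

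Granulin (Grn), a secreted growth factor, was examined because it is the gene the study of this series is known for, a choice that may rest on these same arrays. At its brightest probe set, granulin averaged 10.64 ± 0.11 (SD, n = 5) in Instigator arrays, 10.41 ± 0.14 (SD, n = 5) in Non-instigator arrays and 10.46 ± 0.20 (SD, n = 4) in Matrigel arrays. It was 0.24 higher in Instigator than in Non-instigator arrays (SE 0.10, 95% confidence interval 0.03 to 0.45, 1.18-fold), with a two-sided exact permutation p of 0.0159. The difference did not pass limma's test over all probe sets (adjusted p = 0.813). The other 2 granulin probe sets carry the x_at suffix, which marks sets whose probes match further transcripts. Both separated the tumour groups with no overlap, by 0.51 (SE 0.13) and 0.38 (SE 0.13), each with an exact permutation p of 0.00794, the smallest that 5 against 5 arrays can give. Instigator 5, whose description names the other tumour type, lay at 10.28 and 10.35 there, above the lowest Instigator array (10.21 and 10.17). Counted as Non-instigator it would end the separation, and the difference at the brightest probe set was then 0.16. No exact permutation test was run with it moved. Adjusted over the family of 9 granulin tests, the exact permutation p was 0.0476 at the brightest probe set and 0.0357 at each of the other 2. That family does not cover the choice of granulin itself, so these p are not those of an independent test. On the array with the extreme control values, Instigator 4, granulin was the highest of all 14 arrays at both of those probe sets. Without it the 3 differences were 0.23, 0.39 and 0.26, with exact permutation p of 0.0397, 0.0159 and 0.0159. Adjusted over the same family, these exact permutation p were 0.0893, 0.0714 and 0.0714, so that none passed without that array. The x_at sets still separated the groups without it, since the highest Non-instigator values were 10.06 and 10.15. Fewer arrays give the test fewer splits, so the lost pass does not mean that the separation rests on Instigator 4.

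Against Matrigel, granulin in Instigator arrays was higher by 0.19 at the brightest probe set (SE 0.11, 95% confidence interval -0.04 to 0.41, exact permutation p = 0.111, limma adjusted p = 0.541), a difference within the spread of the arrays. It was 0.10 without Matrigel 3 and 0.09 without Instigator 4 and Matrigel 3, and at the x_at sets 0.17 and 0.13 with all arrays and 0.05 and 0.01 without Instigator 4. At the x_at set with the larger difference the Non-instigator arrays lay below Matrigel by -0.34 (exact permutation p = 0.0238, 0.0536 adjusted over the family of 9), and at the brightest probe set by -0.05 (exact permutation p = 0.651). Kit, the receptor selected against in the sort, averaged 7.58 ± 0.22 (SD, n = 5) in Instigator, 7.37 ± 0.45 (SD, n = 5) in Non-instigator and 7.52 ± 0.37 (SD, n = 4) in Matrigel arrays. At this brighter of its probe sets, Instigator lay above Non-instigator by 0.21 (exact permutation p = 0.373). At its dimmer probe set the Non-instigator arrays lay below Matrigel by -0.31 (95% confidence interval -0.60 to -0.02, exact permutation p = 0.0952) and the Instigator arrays by -0.27 (exact permutation p = 0.167).

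**Figure D2:**
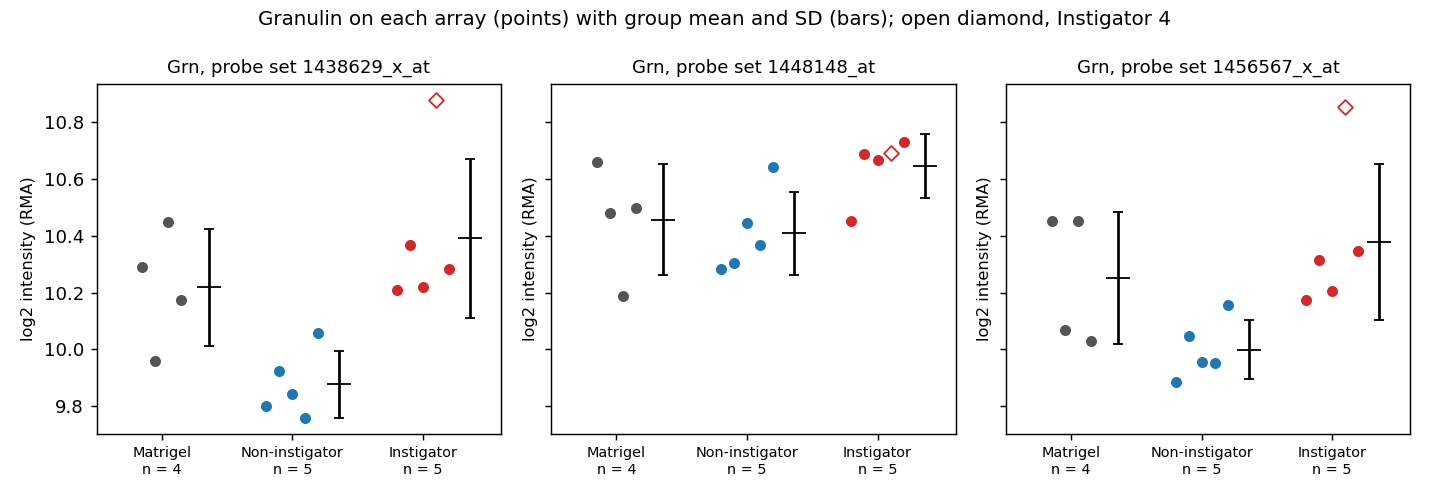
Granulin (Grn) log2 RMA intensity (y axis) on each array (points) at 3 probe sets, by group (x axis), with bars for the group mean and SD and Instigator 4 as the open diamond. At both x_at sets the 5 Instigator arrays lie above the 5 Non-instigator arrays, while at the brightest set the groups overlap and differ by 0.24 on average.

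The first comparison, Instigator against Matrigel, asks what an instigating tumour changes in these marrow cells. Dendritic cell markers lay lower in Instigator arrays, with a median difference of -0.62 over 15 measured genes, 13 of them below 0 (camera adjusted p = 1.1e-05, and adjusted p = 0.589 with an estimated correlation). The C-type lectins Cd209a and Cd209d differed by -1.11 (SE 0.33) and -0.95 (SE 0.35), and the transcription factor Spib by -0.77 (SE 0.28). Neutrophil and granulocyte precursor genes lay higher, with a median of 0.20 and 16 of 17 genes above 0 (camera adjusted p = 1.2e-05, and adjusted p = 0.463 with an estimated correlation). Among them the collagenase Mmp8 differed by 0.44 (SE 0.14), lactoferrin (Ltf) by 0.43 (SE 0.17) and the neutrophil surface antigen Cd177 by 0.43 (SE 0.15).

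B-lineage genes had a median difference of -0.46, with 17 of 20 genes lower in Instigator arrays (camera adjusted p = 0.000265, and adjusted p = 0.697 with an estimated correlation). The surrogate light chain gene Igll1 differed by -0.88 (SE 0.24), the B cell antigen Ms4a1 by -0.73 (SE 0.36) and the receptor component Cd79b by -0.69 (SE 0.28). Without Instigator 3, whose B-lineage mean of 7.87 lay below the 8.64 to 8.94 of the other Instigator arrays, the median was -0.25 (adjusted p = 0.0748). All 13 plasma cell genes were lower, by a median of -0.40 (camera adjusted p = 0.000834, and adjusted p = 0.697 with an estimated correlation), among them syndecan 1 (Sdc1) at -0.94 (SE 0.36) and Irf4 at -0.74 (SE 0.37). Matrigel 3 had the highest plasma cell mean of its group, 9.55, and without it the median was -0.18 (adjusted p = 0.00373).

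Of 12 basophil, mast cell and eosinophil genes, 10 were higher, with a median of 0.46 (camera adjusted p = 0.00478, and adjusted p = 0.589 with an estimated correlation). Alox15 differed by 0.82 (SE 0.39), the mast cell carboxypeptidase Cpa3 by 0.77 (SE 0.39) and the histidine decarboxylase gene Hdc by 0.66 (SE 0.25). Both arrays that stood apart bear on this list, since Instigator 4 had the highest mean of the 14 arrays (8.36) and Matrigel 3 the lowest (7.06). The median was 0.29 without Instigator 4 (adjusted p = 0.0172), 0.30 without Matrigel 3 (adjusted p = 0.425) and 0.12 without both (adjusted p = 0.810). Hypoxia and glycolysis genes had a median of 0.16, with 14 of 16 higher (camera adjusted p = 0.00478, and adjusted p = 0.589 with an estimated correlation), including lactate dehydrogenase A (Ldha) at 0.54 (SE 0.22) and the oxygen sensor Egln3 at 0.43 (SE 0.14). Without Instigator 4 that median was 0.11, and with the mean of each gene's probe sets 0.09.

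Proliferation genes had a median of 0.13, with 17 of 21 higher (camera adjusted p = 0.0264, and adjusted p = 0.697 with an estimated correlation). The replicative helicase subunit Mcm2 differed by 0.56 (SE 0.23) and the mitotic kinase Aurkb by 0.45 (SE 0.18). Leaving out Matrigel 2, Matrigel 3, Instigator 1 or Instigator 3 ended that call, with adjusted p of 0.110, 0.228, 0.124 and 0.112 and medians of 0.08 to 0.11. The call also ended with quantile normalization (adjusted p = 0.0773) and with each array centred on its median (adjusted p = 0.0644). The latter ended the basophil call as well (adjusted p = 0.0506).

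No single gene passed limma's test in this comparison. The count was 0 of 22626 probe sets, with a smallest adjusted p of 0.439. At an unadjusted p under 0.05 there were 2324 probe sets, where a rate of 0.05 gives 1131. Of these, 740 were higher and 1584 lower in Instigator arrays, but quantile normalization gave 1298 higher and 1198 lower, and centring on the median gave 1772 and 961. Without Matrigel 3 there were 739 higher and 835 lower, and there were 784 and 768 without Instigator 4 and Matrigel 3. Adjusted over the list alone, 10 list members passed, against 0 adjusted over all genes. They were 8 dendritic cell genes, Igll1 and Sparc, a secreted matrix protein of the mesenchymal list that differed by -0.82 (SE 0.20).

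Among the 10 genes with the smallest p that were higher, Pole, the catalytic subunit of DNA polymerase epsilon, averaged 8.48 ± 0.26 (SD, n = 5) in Instigator and 7.77 ± 0.20 (SD, n = 4) in Matrigel arrays. The replication licensing factor Cdt1 differed by 0.68 (SE 0.18) and the maintenance DNA methyltransferase Dnmt1 by 0.49 (SE 0.11). Cpt1a and Slc25a20, which carry fatty acids into mitochondria as carnitine esters, differed by 1.08 (SE 0.29) and 0.36 (SE 0.08). Matrigel 3 had a Cpt1a value of 8.06 against 9.45 to 9.56 in the other Matrigel arrays. The others were Lasp1, Lyst, B3galt6, Cdkl2 and Gars. Among those lower, the RNA polymerase III subunit Polr3f differed by -0.62 (SE 0.11) with the smallest p of the comparison, and the RecQ helicase Wrn differed by -0.40 (SE 0.08). Impact, Thoc2 and Tnfrsf19 differed by -0.61, -0.79 and -0.96, and the remaining genes were Gm17546, Tm2d1, Pibf1, Tgds and Sparc. Each of these 20 genes had an adjusted p of 0.439. Several values rest on 1 probe set, since with the mean of each gene's probe sets Wrn differed by -0.11, Cdt1 by 0.43, Thoc2 by -0.47 and Tnfrsf19 by -0.42. The values of Dnmt1, Cpt1a and Lasp1 come from x_at sets, which may match further transcripts. With the mean of its probe sets Dnmt1 differed by 0.40, and Lasp1 by 0.33 against 0.56 at its x_at set. Cpt1a differed by 0.71 without Matrigel 3 and by 0.52 without Instigator 4 and Matrigel 3.

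Without Instigator 4, 1 probe set was called, the dimmer set of the stearoyl-CoA desaturase gene Scd2, singled out here after its values were seen. It averaged 9.17 ± 0.20 (SD, n = 4) in Matrigel arrays and 8.53 ± 0.08 (SD, n = 5) in Non-instigator arrays, and lay at 8.33 to 8.48 in the 4 other Instigator arrays but at 6.35 on Instigator 4. Its difference was -1.18 with all arrays (limma adjusted p = 0.439) and -0.76 without Instigator 4 (limma adjusted p = 0.0306). The brighter set differed less, at 10.70 ± 0.10 (SD, n = 4) in Matrigel and 10.40 ± 0.21 (SD, n = 5) in Instigator arrays.

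The remaining 18 lists were not called in this comparison. Their medians ran from -0.16 for T cell genes to 0.06 for oxidative phosphorylation genes, with camera adjusted p from 0.0561 to 0.910. For the secreted growth factor and matrix remodelling list the median was negative and the mean positive. By exact permutation of the list means per array, 5 lists had p under 0.05, with the smallest at 0.00794 for the granulocyte list, and none passed after adjustment over the 25 lists (smallest adjusted exact permutation p = 0.198).

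**Figure D3:**
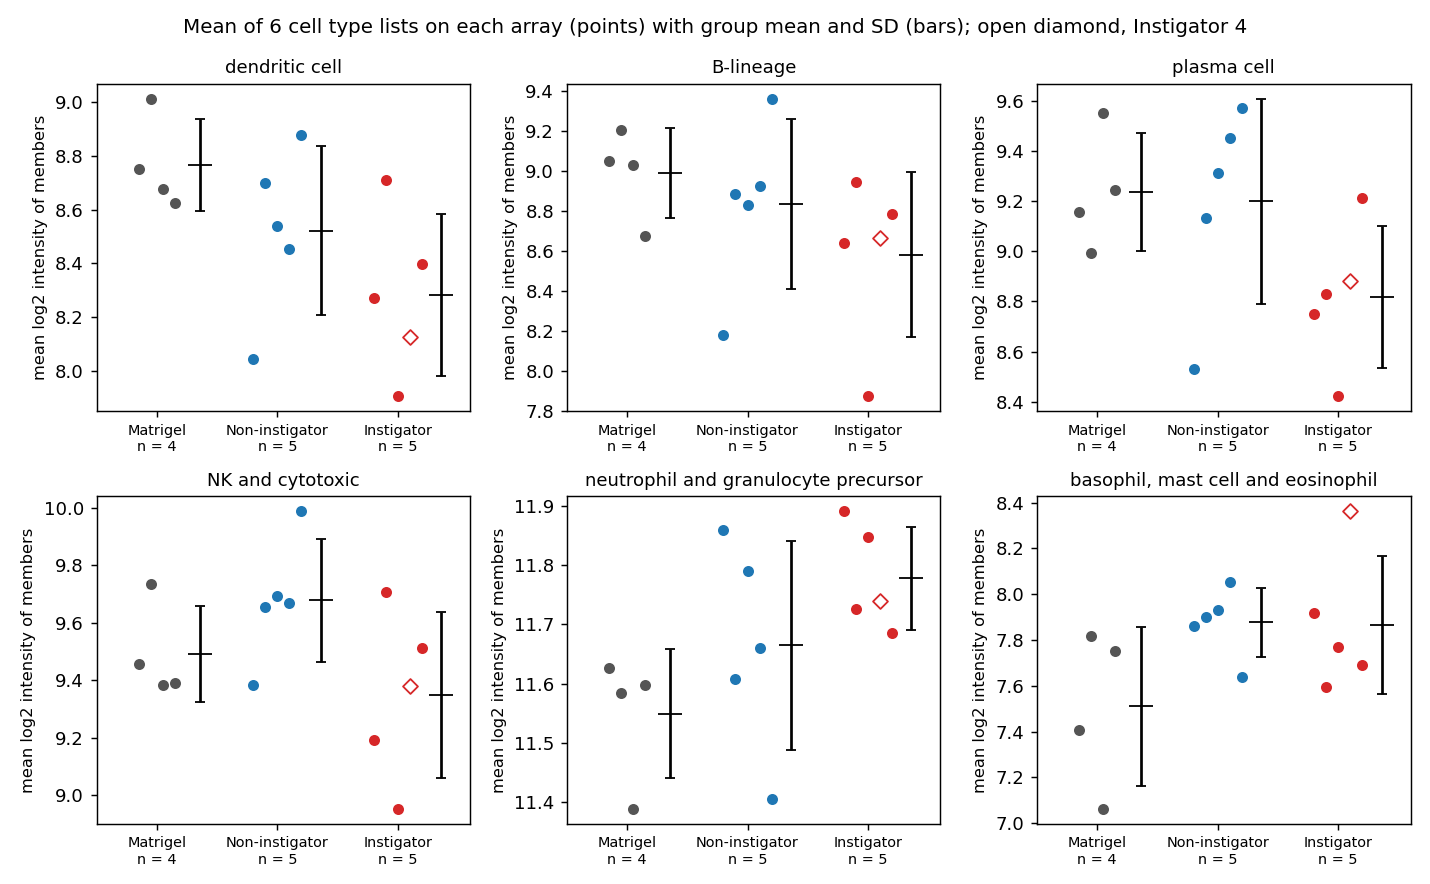
Mean log2 RMA intensity of the members of 6 cell type lists (y axis) on each array (points) by group (x axis), with bars for the group mean and SD and Instigator 4 as the open diamond. Dendritic cell means average 8.28 in Instigator and 8.77 in Matrigel arrays, and B-lineage means run from 7.87 to 8.94 within the Instigator group.

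The second comparison, Non-instigator against Matrigel, asks what a tumour of matched size without instigating activity changes. All 12 basophil, mast cell and eosinophil genes were higher in Non-instigator arrays, by a median of 0.37 (camera adjusted p = 1.2e-06, and adjusted p = 0.264 with an estimated correlation). Alox15 differed by 0.72 (SE 0.39), the basophil protease Mcpt8 by 0.57 (SE 0.25) and eosinophil peroxidase (Epx) by 0.45 (SE 0.37). NK and cytotoxic genes had a median of 0.20, with 13 of 15 higher (camera adjusted p = 6.6e-06, and adjusted p = 0.479 with an estimated correlation), including the interleukin 2 receptor chain Il2rb at 0.43 (SE 0.22) and the transcription factor Eomes at 0.41 (SE 0.23). Neutrophil and granulocyte precursor genes had a median of 0.13, with 12 of 17 higher (camera adjusted p = 0.000118, and adjusted p = 0.407 with an estimated correlation), among them Mmp8 at 0.37 (SE 0.14). Matrigel 3 had the lowest mean of its group for the basophil list (7.06) and the granulocyte list (11.39), and without it the medians were 0.20 and 0.07.

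Dendritic cell genes were lower in 14 of 15 cases, with a median of -0.31 (camera adjusted p = 0.00253, and adjusted p = 0.690 with an estimated correlation). Cd209a differed by -0.51 (SE 0.33) and the chemokine receptor Ccr9 by -0.41 (SE 0.26). Type I interferon response genes had a median of -0.14, with 12 of 17 lower (camera adjusted p = 0.0237, and adjusted p = 0.739 with an estimated correlation), including Usp18 at -0.68 (SE 0.26) and Oas1a at -0.42 (SE 0.20). Leaving out Matrigel 1, Matrigel 2 or Non-instigator 1 ended both calls. The adjusted p without each was 0.0641, 0.259 and 0.197 for the dendritic list and 0.126, 0.201 and 0.488 for the interferon list. The interferon call also ended with the brighter probe sets alone (adjusted p = 0.0813), its median was -0.23 without Matrigel 4 and -0.09 with quantile normalization or centring, and the dendritic median was -0.16 without Non-instigator 1.

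Erythroid genes had a median of 0.15, with 12 of 14 higher (camera adjusted p = 0.00723, and adjusted p = 0.690 with an estimated correlation), including Rhag at 0.32 (SE 0.21). T cell genes had a median of 0.08 with 14 of 17 higher (camera adjusted p = 0.0387, and adjusted p = 0.799 with an estimated correlation), including the interleukin 7 receptor Il7r at 0.42 (SE 0.34). Hypoxia and glycolysis genes had a median of 0.07 with 10 of 16 higher (camera adjusted p = 0.0387, and adjusted p = 0.690 with an estimated correlation), including pyruvate kinase (Pkm) at 0.37 (SE 0.19). The erythroid call ended without Matrigel 3, Matrigel 4 or Non-instigator 5 (adjusted p of 0.174, 0.0779 and 0.0852) or with quantile normalization (adjusted p = 0.0505). Its median was 0.08 without Matrigel 3 and 0.22 without Non-instigator 4. The erythroid call also ended without Instigator 4 and Matrigel 3, with a median of 0.08. The T cell call ended without Matrigel 1, Matrigel 4, Non-instigator 4 or Non-instigator 5, with medians of 0.08, 0.03, -0.06 and -0.04, and its median was 0.26 without Non-instigator 1, 0.14 without Matrigel 2 and 0.15 without Matrigel 3 or Non-instigator 3. It also ended with the brighter probe sets alone (adjusted p = 0.128), with quantile normalization (0.112), with centring on the median (0.183) and with Instigator 5 counted as Non-instigator (0.0778). With the replicate number as a block the T cell call ended too, with a median of -0.01. The hypoxia call ended without Matrigel 2, Matrigel 3, Non-instigator 1 or Non-instigator 2, with medians of -0.01, 0.06, 0.00 and 0.07, and its median was 0.04 without Matrigel 4. It also ended with the brighter probe sets alone (adjusted p = 0.0635), with quantile normalization (0.0971), with the mean of each gene's probe sets (median 0.01, adjusted p = 0.157) and without Instigator 4 and Matrigel 3 (0.150), and its median was 0.13 with centring on the median.

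No probe set passed limma's test, with 0 of 22626 called and a smallest adjusted p of 0.986. At an unadjusted p under 0.05 there were 477, where a rate of 0.05 gives 1131, with 136 higher and 341 lower. Quantile normalization gave 245 and 244, and centring on the median 274 and 201. Without Matrigel 3 there were 84 higher and 98 lower. The count was 1279, 892, 182 and 797 without Matrigel 1, 2, 3 and 4, and 836 without Instigator 4, which enters through the shared estimate of the spread. It was 827 with array weights. List members called were 0 adjusted over the list alone and 0 adjusted over all genes.

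The 10 genes with the smallest p that were higher were led by Slc25a20, at 9.89 ± 0.09 (SD, n = 5) in Non-instigator and 9.54 ± 0.18 (SD, n = 4) in Matrigel arrays. Il1r2, the decoy receptor for interleukin 1, differed by 0.62 (SE 0.20) and the lysosomal acetyltransferase Hgsnat by 0.26 (SE 0.08). Dennd2d, Arap3, Anxa6, Kcnab2, Sh2d2a, Ulk1 and Osbpl5 completed them. Among the 10 lower, the interferon-inducible Ifi202b averaged 9.90 ± 0.53 (SD, n = 5) against 10.98 ± 0.49 (SD, n = 4), and Vhl, the recognition subunit of the ligase for hypoxia-inducible factors, differed by -0.43 (SE 0.11). Zeb2 differed by -0.55 (SE 0.17), with 6.43 on Matrigel 3 and 5.66 to 5.72 on the other Matrigel arrays, and differed by -0.37 without Matrigel 3. Vhl differed by -0.24 with array weights. Uevld, Ankrd27, Snai1, Scd2, Ifi30, Sox4 and Ankrd49 completed them. Each of the 20 had an adjusted p of 0.986.

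The 17 lists not called had medians from -0.19 for B-lineage genes to 0.03 for proliferation genes, with camera adjusted p from 0.224 to 0.967. Median, mean and test differed in sign for 7 lists, namely stem and progenitor, plasma cell, inflammatory, ribosomal protein, oxidative phosphorylation, unfolded protein response and antigen presentation genes. By exact permutation of the list means, 0 lists had p under 0.05 (smallest exact permutation p = 0.0635, for the basophil list).

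The third comparison, Instigator against Non-instigator, asks what separates marrow cells of mice with the 2 tumour kinds at matched size. NK and cytotoxic genes were lower in Instigator arrays in 14 of 15 cases, with a median of -0.30 (camera adjusted p = 1.1e-07, and adjusted p = 0.496 with an estimated correlation). The activating receptor genes Klrk1 and Ncr1 differed by -0.74 (SE 0.36) and -0.59 (SE 0.23), and Il2rb by -0.59 (SE 0.20). All 17 T cell genes were lower, by a median of -0.24 (camera adjusted p = 7.4e-06, and adjusted p = 0.496 with an estimated correlation), including Cd2 at -0.63 (SE 0.22) and the receptor zeta chain Cd247 at -0.51 (SE 0.16). All 13 plasma cell genes were lower, by a median of -0.35 (camera adjusted p = 2.9e-06, and adjusted p = 0.496 with an estimated correlation), including Eaf2 at -0.78 (SE 0.32) and the survival receptor Tnfrsf17 at -0.66 (SE 0.24). B-lineage genes were lower in 18 of 20 cases, by a median of -0.28 (camera adjusted p = 0.000371, and adjusted p = 0.593 with an estimated correlation), including Igll1 at -0.63 (SE 0.22).

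Single arrays weighed on these lymphoid lists. Without Instigator 3 the medians were -0.19 for plasma cell, -0.15 for T cell and -0.04 for B-lineage genes, and without Non-instigator 5 they were -0.21, -0.14 and -0.10. The B-lineage call ended in both cases (adjusted p of 0.235 and 0.0608), and its median was -0.50 without Non-instigator 1 and -0.18 without Non-instigator 4. The T cell median was -0.37 without Non-instigator 1. By exact permutation of the list means per array, p was 0.0952 for the NK, 0.119 for the plasma cell, 0.262 for the T cell and 0.349 for the B-lineage list.

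Dendritic cell genes had a median of -0.26, with 11 of 15 lower (camera adjusted p = 0.00648, and adjusted p = 0.593 with an estimated correlation), including Cd209d at -0.91 (SE 0.33). Without Instigator 3 or Non-instigator 5 this call ended (adjusted p of 0.141 and 0.108), and the median was -0.15 without Instigator 4 and -0.43 without Non-instigator 1. The call also ended with the brighter probe sets alone (adjusted p = 0.0967), and with the mean of each gene's probe sets the median was -0.10. Erythroid genes had a median of -0.15, with 11 of 14 lower (camera adjusted p = 0.0017, and adjusted p = 0.496 with an estimated correlation), including the haem synthesis enzyme Alas2 at -0.59 (SE 0.28) and Rhag at -0.50 (SE 0.20). Its call held without any 1 array, with medians of -0.28 without Instigator 1, -0.08 without Instigator 3 or Non-instigator 5, -0.25 without Instigator 4, -0.09 without Non-instigator 2 and -0.26 without Non-instigator 4.

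Lysosome genes were the 1 list called in the higher direction in Instigator arrays, with a median of 0.10 and 17 of 20 genes above 0 (camera adjusted p = 0.0179, and adjusted p = 0.496 with an estimated correlation). The sorting receptor Sort1, which binds granulin, differed by 0.34 (SE 0.20), and the membrane glycoprotein Lamp2 by 0.19 (SE 0.08). Without Instigator 2 the call ended (adjusted p = 0.0678), and with the mean of each gene's probe sets the median was 0.06 (adjusted p = 0.346). Without Instigator 4 and Matrigel 3 the call ended as well (adjusted p = 0.0714). Ribosomal protein genes had a median of -0.09, with 12 of 15 lower (camera adjusted p = 0.0374, and adjusted p = 0.593 with an estimated correlation), including Rps19 at -0.25 (SE 0.20). Unfolded protein response genes had a median of -0.11, with 12 of 18 lower (camera adjusted p = 0.0150, and adjusted p = 0.496 with an estimated correlation), including the chaperone Hsp90b1 at -0.38 (SE 0.18). Both lists moved with Instigator 4, whose ribosomal mean of 11.9 lay below the 12.1 to 12.2 of the other Instigator arrays, and without it the medians were -0.01 and -0.04 (adjusted p of 0.635 and 0.102). The ribosomal call also ended without Instigator 5, Non-instigator 1 or Non-instigator 2 (adjusted p of 0.0674, 0.0991 and 0.0659) and with quantile normalization (adjusted p = 0.0541), with the brighter probe sets alone (0.0632) or with Instigator 5 counted as Non-instigator (0.0906). It ended as well with the replicate number as a block and without Instigator 4 and Matrigel 3. The unfolded protein call also ended without Non-instigator 1 (adjusted p = 0.0507), with the brighter probe sets alone (0.0641) and without Instigator 4 and Matrigel 3.

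No probe set passed limma's test, with 0 of 22626 called and a smallest adjusted p of 0.813. At an unadjusted p under 0.05 there were 1268, where a rate of 0.05 gives 1131, with 507 higher and 761 lower in Instigator arrays. Quantile normalization gave 680 and 667, and centring on the median 817 and 666. Without Matrigel 3, which enters through the shared estimate of the spread, there were 876 higher and 899 lower. There were 953 higher and 763 lower without Instigator 4 and Matrigel 3. The count was 1936, 832, 714 and 717 without Non-instigator 1, 3, 4 and 5. It was 2763 with array weights, and 2126 with Instigator 5, whose description names the other tumour type, counted as Non-instigator. List members called were 0 adjusted over the list alone and 0 adjusted over all genes.

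The endosomal scaffold subunit Lamtor1 had the smallest p among the 10 genes that were higher, at 12.35 ± 0.13 (SD, n = 5) in Instigator and 11.95 ± 0.16 (SD, n = 5) in Non-instigator arrays. The cytokine Lif differed by 0.31 (SE 0.08), the high-affinity IgG receptor Fcgr1 by 0.70 (SE 0.19) and the macrophage lectin Siglec1 by 0.28 (SE 0.08). Dnmt1, Cdkl2, Sh2b2, Dync1i1, Hr and Dnajc10 completed them. Among the 10 lower, Polr3f differed by -0.50 (SE 0.10), S1pr5, a sphingosine 1-phosphate receptor of NK cells, by -0.62 (SE 0.14) and Sh2d1a, an adaptor in T and NK cells, by -0.81 (SE 0.22). The mast cell chymase Cma1 differed by -0.69 (SE 0.19). Rab27b, Zyg11b, Serpinb9b, Rida, Wrn and Gm17546 completed them. Each of the 20 had an adjusted p of 0.813. With the mean of each gene's probe sets Lamtor1 differed by 0.14, Lif by 0.13, Siglec1 by 0.10 and Polr3f by -0.28. With Instigator 5 counted as Non-instigator Polr3f differed by -0.29.

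The 16 lists not called had medians from -0.04 for megakaryocyte and platelet genes to 0.16 for type I interferon genes, with camera adjusted p from 0.0903 to 0.951. Median, mean and test differed in sign for the stem and progenitor, the basophil and the immediate early lists. By exact permutation of the list means, 2 lists had p under 0.05, with the smallest at 0.0317 for the lysosome list, and none passed after adjustment (smallest adjusted exact permutation p = 0.504).

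For the 2 joint questions, what both tumour groups share against Matrigel and what sets Instigator arrays apart from both other groups, the count of probe sets called in 1 direction was 0 in each case. Differences of the tumour groups from Matrigel correlated at r = 0.551 across probe sets, which are not independent replicates, and simulated unchanged groups sharing the same Matrigel arrays gave 0.554. The covariance was 0.0165, against 0.0151 simulated, and with the Matrigel arrays split between the comparisons r was 0.0525. At an unadjusted p under 0.05 in both, 60 probe sets were higher and 156 lower, where independent lists give 4.45 and 23.9 and the simulation 147 and 149. Differences of the Instigator arrays from Matrigel and from Non-instigator correlated at r = 0.773, against 0.475 simulated, with a covariance of 0.0305 against 0.0123 and r = 0.295 with the Instigator arrays split. In both of these, 165 probe sets were higher and 437 lower at an unadjusted p under 0.05, where independent lists give 16.6 and 53.3 and the simulation 119 and 121. With the Instigator arrays split, no array enters both comparisons, so the r of 0.295 does not come from sharing Instigator 4. No simulated r stands beside that value. In the other values Instigator 4, which stood apart from the other arrays, enters both comparisons. The r, the covariance and these counts were not computed without it. The excess over the simulation is therefore not read as a change shared by the Instigator group.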

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

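The tests of the beta-actin control, of the other Instigator arrays on the first principal component, of the lymphoid lists and of granulin without Instigator 4 were chosen only after the result was seen. In 264 combinations of a group and a measure, 23 held an array far from the others of its group, where chance gives about 1 in 20, or 13.2. Instigator 4 was the far array in 10 of them and Matrigel 3 in 5.

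Instigator 4 lay at 73.8 on the first principal component and at -10.8 on the second, with a median correlation of 0.963 with the other arrays. Its control differences between 5' and 3' probe sets were -3.41 for beta-actin and -4.03 for Gapdh. Its monocyte and macrophage mean was 8.87 against 8.30 to 8.42 on the other Instigator arrays, and its ribosomal protein mean 11.85 against 12.13 to 12.22. Lasp1 lay at 11.65, Ulk1 at 8.37 and Sh2b2 at 8.50, each above the other Instigator arrays. Matrigel 3 had a median log2 value of 7.18, lay at -55.7 on the second component and had a median correlation of 0.980. Its Cpt1a value was 8.06, below the other Matrigel arrays, and its Zeb2 value 6.43, above them. No explanation was tested for Matrigel 3.

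Single arrays also lay far from their group in 8 other measures. Instigator 3 had a B-lineage mean of 7.87 and a Rab27b value of 6.83, both below the other Instigator arrays. Matrigel 1 had a Dnmt1 value of 11.72 against 11.33 to 11.38 and a Serpinb9b value of 8.35 against 9.24 to 9.34 on the other Matrigel arrays. Instigator 1 had a granulin value of 10.45 at the brightest probe set, against 10.67 to 10.73. Non-instigator 1 had a transferrin receptor control difference of -2.34, Non-instigator 3 a Slc25a20 value of 10.04 and Non-instigator 5 an Ifi202b value of 10.82, each above the rest of that group.

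The first pattern weighed is that Instigator 4 stands apart from the other 13 arrays. The median of the other 4 Instigator arrays on the first component was 1.11, inside the -19.6 to 4.36 of the Matrigel and Non-instigator arrays. This argues against an effect of the instigating tumour common to its group. The component is the one on which Instigator 4 was seen to stand apart, so the median adds little beyond the pattern itself. An effect in Instigator 4 alone stays open. Shorter or degraded RNA templates may account for it, as the beta-actin difference of -3.41 lay below the -0.81 to -0.51 of the other arrays. The transferrin receptor difference of -2.58 met the bound set beforehand against this explanation, but it lay above the lowest other array (-2.71) by less than the SD of 0.21, and its 5' probe set lies below the median of the array on all 14 arrays (5.07 to 6.45), a limit of that test written down after its value was seen. Cells of another type in the sort stay open, since 0.5 of the basophil, mast cell and eosinophil list (6 of 12 genes) and 0.45 of the monocyte and macrophage list lay higher on Instigator 4 than on each other array, against 0.192 of all probe sets, between the bounds set for and against it, although the cKit-negative sort would remove mast cells and Kit was not raised on Instigator 4 (4.65 at the dimmer probe set, the lowest of the 14 arrays, and 7.43 at the brighter, within 6.82 to 8.05).

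The second pattern is that lymphoid lists lay lower in Instigator than in Non-instigator arrays. Instigator 4 is argued against as its source, since the median difference over the 65 lymphoid genes was -0.30 with it and -0.32 without it. A lymphoid cell share that varies between arrays within a group met the bound set for it. The lymphoid score ranged over 0.97 within the Non-instigator group while the group means differed by -0.31 (two-sided exact permutation p = 0.198). A range within a group easily exceeds a difference that does not pass, and the score cannot tell cell share from expression per cell. The test therefore cannot decide, and a varying cell share stays open. An effect of the tumour kind stays open beside it.

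The third pattern is that granulin was higher in Instigator than in Non-instigator arrays. Instigator 4 is argued against as the whole source. At the brightest probe set the difference was 0.23 without it (exact permutation p = 0.0397, and 0.0893 adjusted over the family of 9 tests, where the difference no longer passes). Its value there, 10.69, lay among the other Instigator arrays, so leaving it out could hardly change that difference. At the x_at sets, where it was the highest array, the differences fell from 0.51 to 0.39 and from 0.38 to 0.26. With the mean of 37 granulocyte and monocyte genes as a covariate the difference at the brightest probe set was 0.30 (SE 0.12), against 0.24 without. This met the bound set beforehand against a larger myeloid share of the sort. Yet the granulocyte (11.78 against 11.66) and monocyte (8.47 against 8.37) means were themselves higher in Instigator arrays. A rise of the difference then means that granulin did not increase with this score within groups. The score thus cannot decide the question, and a larger myeloid share stays open. An effect of the tumour kind may account for the higher granulin, as a hypothesis found and tested on the same arrays, and array batch was not tested because the labels give none.

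Chance is not excluded for any of the counts, by 100 splits of the arrays of each comparison into groups of the same sizes, where each number of splits includes the real one. For Instigator against Matrigel, 11 splits gave as many probe sets at an unadjusted p under 0.05 as the real 2324 (highest other 3189), and 25 gave as many called lists as the real 7 (highest other 11). For Non-instigator against Matrigel, 67 splits reached the real 477 (highest other 2529) and 39 the real 8 lists (highest other 13). For Instigator against Non-instigator, 15 splits reached the real 1268 (highest other 3233) and 28 the real 9 lists (highest other 16). No probe set was called by limma in the real splits, while other splits called up to 4, 1 and 6. The median count of called lists in the other splits was 4, 6 and 6. For probe sets at an unadjusted p under 0.05 the median in the other splits was 1300, 618 and 565. The 1131 that a rate of 0.05 gives is therefore no measure of chance on these arrays.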

How the results depend on the processing

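Leaving out Instigator 4 and Matrigel 3 together, the exact permutation of list means and the scalings before the list test were chosen after seeing the data. For Instigator against Matrigel the count of called probe sets was 0 to 1 over the fits without 1 array, with the 1 call without Instigator 4, and 1 without Instigator 4 and Matrigel 3. In the other comparisons it stayed at 0 under each alternative run. With an estimated correlation, and by exact permutation of the list means, 0 lists were called in each of the 3 comparisons, against 7, 8 and 9. Without 1 array the count of lists ranged from 6 to 10 for Instigator against Matrigel, from 5 to 9 for Non-instigator against Matrigel (5 without Matrigel 1 or Matrigel 2) and from 8 to 13 for Instigator against Non-instigator. Quantile normalization before the list test gave 5 lists for Non-instigator against Matrigel. With the replicate number as a block, 11 lists were called for Instigator against Matrigel, while for Non-instigator against Matrigel the T cell call ended with a median of -0.01 (adjusted p = 0.345), and for Instigator against Non-instigator the ribosomal protein call ended (adjusted p = 0.0531). The numbers are not taken as a pairing, since 2 of 14 arrays correlated best with an array of their own number. The estimated correlation ran from 0.0116 to 0.603 over the lists, where the preset was 0.01, and a larger correlation widens the error of a list. For the other alternatives the cause was not tested. No called result reversed in the direction of its test. Called lists kept their call in 443 values under the alternatives, and 85 calls were lost. These counts include fits without an array of neither group compared, which enters only through the shared estimate of the spread. They leave out the exact permutation of the list means, so they overstate how stable the calls are. No named gene passed the threshold, so its side of the threshold says nothing about stability. Granulin in Instigator against Non-instigator arrays differed by 0.21 to 0.30 without 1 array and by 0.16 to 0.38 under the other alternatives, the lowest with Instigator 5 counted as Non-instigator and the highest with the mean of its probe sets (limma adjusted p from 0.379 to 0.983). Signal over background limits probe sets near the floor of the arrays.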

Other observations

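The relation of lymphoid to granulocyte genes and the lists singled out here were chosen after the values were seen. In Instigator against Non-instigator arrays, the monocyte and macrophage list was not called (camera adjusted p = 0.348), with a median of 0.03 and 11 of 20 members above 0. Its members Csf1r, the receptor for colony stimulating factor 1, and Fcgr1 had the largest differences, 0.85 (SE 0.30) and 0.70 (SE 0.19). The monocyte and macrophage mean of Instigator 4 was 8.87, against 8.30 to 8.42 on the other Instigator arrays, and without it Fcgr1 differed by 0.55. Fcgr1 had an adjusted p of 0.0539 over the list alone. Of the secreted growth factor and matrix remodelling list, fibronectin (Fn1) differed by 0.50 (SE 0.19), the urokinase gene Plau by 0.45 (SE 0.24) and Thbs1 by -0.60 (SE 0.21), with a camera adjusted p of 0.223 for the list.

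Across the 14 arrays, the mean of the lymphoid lists and the mean of the granulocyte list were inversely related, with Pearson's r of -0.763 (permutation p = 0.0016, adjusted 0.00236 over 2 relations) and Spearman's rho of -0.741 (permutation p = 0.00375, adjusted 0.0052). Without Instigator 3 and Non-instigator 1, the arrays farthest from the median lymphoid mean, r was -0.722. With each group mean subtracted, r was -0.746 (permutation p = 0.00236) and rho -0.719 (permutation p = 0.0052), and r was -0.743 without the same arrays. The adjustment does not cover the choice of this pair of means, so these permutation p are not those of an independent test.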
